A study of Mus musculus with 18 samples.

How the data were processed

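Gene expression was measured by sequencing total RNA from C57BL/6 mouse cardiomyocytes of postnatal day 7, given LacZ or 4F adenovirus for 24, 48 or 72 h. Per the labels' protocols, RNA was isolated with the miRNeasy Micro kit and libraries were made with the Ovation RNA-seq System v2, which amplifies cDNA before sequencing. Amplification can change the share of reads from short, GC-rich or rare transcripts, and can lower the number of distinct molecules in a library. The submitters' processing notes name HISAT2 and the builds GRCm38 and mm10, without versions. The counting tool, annotation release and strand setting are not given in the sources used here.

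The values analysed are the FPKM that the authors deposited, fragments per kilobase of gene and M of a library size, for 54532 genes in 18 libraries, and no column of another sample was present (0). Gene identifiers were matched to GENCODE M21 on GRCm38, with 54495 found, and 105 symbols belonged to more than 1 gene. In all 18 libraries 21708 genes were at 0. Multiplying each FPKM by the union length of the gene's exons gave steps of 1 number per library, so reads could be recovered. Of the values above 0, 96.6% lay within 0.05 of a whole read. Recovered totals ran from 17.97 to 27.07 M reads per library, and genes with reads from 14647 to 24304. The library sizes behind the values were 1.01 to 1.15 times these totals, and all 18 libraries shared 1 median log2 ratio to the gene means (0.025). The values thus look scaled by median ratios rather than to the read totals, a step not given in the sources used here, and a further median-ratio scaling changes nothing. The deposited values were tested as FPKM, and the recovered reads served as alternatives only.

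Groups and comparisons were taken from the labels. The gene lists, the rule for named genes, the tests and the first set of alternatives were fixed before the data were examined. Genes with FPKM of at least 1 in at least 3 of the 18 libraries were kept (13636). The values log2(FPKM + 1) were fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group, using all 6 groups for a shared spread, contrasts, and eBayes with a trend on mean expression. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts were 4F against LacZ at 24, 48 and 72 h, the average of these, the 48 h and the 72 h effect minus the 24 h effect, and LacZ at 72 h against LacZ at 24 h. All adjusted p-values given for genes come from limma.

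Of 36 gene lists, 33 had at least 3 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists of a comparison. The lymphocyte and erythroid marker lists had 0 measured members. The Schwann cell list had 1, S100b, with a log2 fold change of -0.37 ± 0.22 at 72 h (limma adjusted p = 0.198). Camera was repeated with a correlation estimated from the data, and fry was run beside it. Of the lists called at 24, 48 and 72 h (17, 20 and 23), 11, 13 and 12 held with an estimated correlation, as did 17 of 26 for the average, 9 of 15 for 72 h minus 24 h and 10 of 14 for LacZ over time. The median of a list and its test differed in sign in 1, 1 and 2 lists at 24, 48 and 72 h, in 2 for 72 h minus 24 h and in 1 for LacZ over time. Members are counted as higher or lower by their adjusted p over all genes tested, and again adjusted over the list alone. Lists share members, such as Pmaip1 and Bbc3 in the p53 and pro-apoptotic lists.

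Genes named in the text are the 4 factor genes, the 10 genes highest and the 10 lowest in log2 fold change at each time, and 5 each for the differences over time and LacZ over time. Apart from the 4 factor genes, these needed a call, a mean FPKM of at least 5 in the higher group and a given gene name. No overlap between the groups was also needed, except for the differences over time. From each list at most 4 called members were named, or 2 with the smallest p where none was called. Members outside this rule are marked in the text, and some genes the rule selects are not reported here.

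Alternatives set beforehand were pseudocounts of 0.1 and 0.5, a filter at FPKM 5 and no filter, quantile normalization, median-ratio scaling, limma without the trend, robust or with weights per library, only the groups compared, a minimum log2 fold change of 1, a replicate block, and each library left out in turn. Chosen after the data were seen were scaling to the recovered reads, voom on them, leaving out the 4 low-complexity libraries (under 10% of detected genes at 1 to 3 reads), the same share as a covariate, and a correction for GC content. That correction subtracts a lowess trend (span 0.3) of each library's deviation on the GC share of the longest transcript. Versions were statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

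The fit was tested on simulated data for 4F against LacZ at 24 h, with 200 of 13636 genes changed. It recovered 50.7%, 91.0% and 98.5% of those changed by 0.5, 1 and 2 on the log2 scale, with 17 false calls, 9.60% of the calls. With a GC trend added to the simulation, steeper than in the data (rank correlation across genes -0.70), the fit made 2201 false calls without the GC correction and 17 with it. A simulated list shifted by 0.5 was called and 0 unchanged lists were. The genes were simulated as independent, so this does not test list calls where members are correlated. Replicate pairs were compared by a chi-square test of their recovered reads, and all differed by more than sampling noise (chi-square per degree of freedom from 3.52 to 147). Reads are not separated by molecular identifiers, so amplified copies count as reads, and values of genes with near-identical copies are uncertain.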

Results

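RNA was sequenced from cardiomyocytes isolated from C57BL/6 mice at postnatal day 7 and exposed to adenovirus for 24, 48 or 72 h. The virus delivered either LacZ, a bacterial beta-galactosidase used as a control, or the 4 cell cycle factors of the series title, called 4F in the labels. Each of the 6 groups of treatment and time held 3 libraries, 18 in all. The labels do not say that the 3 libraries came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical. The deposited values gave back 17.97 to 27.07 M reads per library, and 13636 genes were tested. Levels below are mean FPKM ± SD (n = 3), and fold changes are log2 differences ± SE on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. In 4 libraries, LacZ 24 h replicate 3, LacZ 72 h replicate 1 and 4F 48 h replicates 1 and 3, only 2.45% to 5.61% of the detected genes had 1 to 3 reads, a sign of low library complexity, against at least 12.7% in each of the others. LacZ 24 h replicate 3 and LacZ 72 h replicate 1 also stood apart in markers of other cell types. Fibroblast markers had a mean log2(FPKM + 1) of 4.35 and 4.37 there, against 5.06 and 5.08 in the other LacZ libraries of 24 h and 4.72 and 4.86 in those of 72 h. Smooth muscle and pericyte markers stood at 3.95 in LacZ 24 h replicate 3, against 3.66 and 3.69 in the other LacZ libraries of 24 h, and endothelial markers at 3.38 against 3.68 and 3.69. For macrophage markers, the mean log2(FPKM + 1) was 2.37 in LacZ 24 h replicate 3 and 2.47 in LacZ 72 h replicate 1, against 3.11 to 3.34 in the other LacZ libraries of those times.

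The labels do not name the 4 factors. Work in this field has used CDK1 and cyclin B1, which drive entry into mitosis, with CDK4 and cyclin D1, which act in G1, so the mouse genes for these were read first. Cdk1 (ENSMUSG00000019942, chromosome 10, 69335146 to 69352938, GRCm38) rose at 24 h from 14.02 ± 6.03 FPKM with LacZ to 36.8 ± 0.861 FPKM with 4F, a log2 fold change of 1.43 ± 0.24. The low-complexity library LacZ 24 h replicate 3 lowered that LacZ mean, with 7.07 FPKM against 17.8 and 17.1 in replicates 1 and 2. Its 48 and 72 h log2 fold changes were 0.99 ± 0.24 and 1.17 ± 0.24. Ccnb1 (ENSMUSG00000041431, chromosome 13, 100778650 to 100786570) rose by 1.19 ± 0.067, 1.08 ± 0.067 and 1.43 ± 0.067 on the log2 scale at 24, 48 and 72 h, reaching 33.3 ± 1.28 FPKM at 72 h against 11.7 ± 0.143 with LacZ. Cdk4 (ENSMUSG00000006728, chromosome 10, 127063534 to 127067920) did not pass the test at any time, with 66.3 ± 3.26 FPKM with LacZ and 76.4 ± 2.53 with 4F at 24 h and adjusted p-values of 0.0924, 0.129 and 0.576 at 24, 48 and 72 h. At 24 h its values were 62.6 to 68.8 FPKM with LacZ and 73.6 to 78.4 with 4F. After the GC correction Cdk4 was called higher at 24 h, where 3 of the 4 genes were higher and 1 lower. Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925) was lower with 4F at each time, with log2 fold changes of -0.72 ± 0.12, -0.59 ± 0.12 and -0.82 ± 0.12, and stood at 63.7 ± 1.15 FPKM at 72 h against 114 ± 20.3 with LacZ. Whether reads from the viral transgenes align to the mouse genes is not given in the sources used here, so these values do not show the level of the delivered factors. As a list, the 4 genes were not called against all other genes at 24 h (limma camera, adjusted p = 0.119, or 0.0447 after the GC correction), at 48 h (adjusted p = 0.0918) or at 72 h (adjusted p = 0.502), with 2 higher and 1 lower each time over all genes tested. Adjusted over the list alone, 3, 2 and 2 were higher and 1, 1 and 1 lower at the 3 times.

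**Figure D1:**
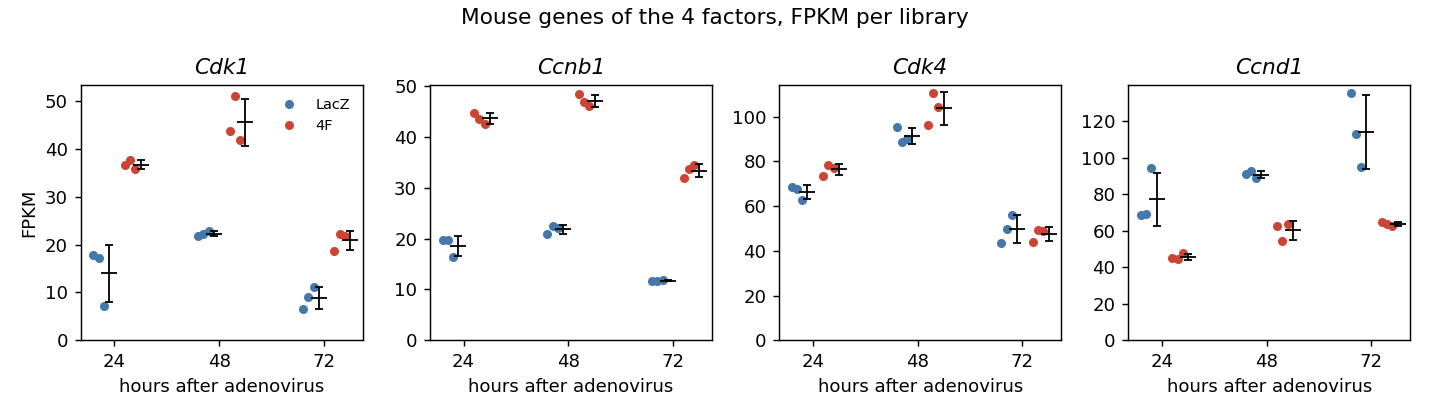
FPKM (y axis) of Cdk1, Ccnb1, Cdk4 and Ccnd1 in each library against hours after adenovirus (x axis), LacZ in blue and 4F in red, where each point is 1 library and black marks are the mean ± SD of 3 libraries. Cdk1 and Ccnb1 were higher and Ccnd1 lower with 4F at 24, 48 and 72 h. Cdk4 did not pass the test at any time, but was called higher at 24 h after the GC correction.

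The comparison of 4F with LacZ at 24 h asked which transcripts differed early after delivery of the factors. Genes of the cell cycle rose together, and genes of the contractile apparatus fell. E2f8, an E2F family repressor expressed in cycling cells, rose from 3.38 ± 0.222 to 19.9 ± 0.535 FPKM, a log2 fold change of 2.26 ± 0.090. Cdt1, which licenses replication origins, rose by 2.22 ± 0.19, and Pclaf, a PCNA-binding protein, by 2.13 ± 0.10. Myh6, the alpha myosin heavy chain of the mouse heart, fell from 1413 ± 358 to 703 ± 18.96 FPKM. Of 13636 genes, 3827 were called at an adjusted p below 0.05 by limma, 1997 higher and 1830 lower with 4F. Of these, 334 were higher and 31 lower by at least 1 on the log2 scale. The split was 2541 higher and 1382 lower when scaled to recovered reads, and 1764 and 2138 with quantile normalization.

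Every one of the 45 G1/S and DNA replication genes rose at 24 h (45 adjusted over the list alone), with a median log2 fold change of 1.38 (camera adjusted p = 4.68e-43). Of 35 G2/M and mitosis genes 31 rose (31 adjusted over the list alone, median 1.19, camera adjusted p = 8.91e-27). Examples were the kinesin Kif11 (1.88 ± 0.12), the spindle protein Ckap2l (1.63 ± 0.086) and the mitotic kinase Aurka (1.58 ± 0.084). The 4 that were not called, Cenpe, Cenpf, Mki67 and Pttg1, were singled out after their values were seen. Cytokinesis genes rose in 11 of 13 cases (11 adjusted over the list alone, median 1.06, camera adjusted p = 7.13e-12). Among these were Cep55 (1.60 ± 0.093), which acts in abscission, and Ect2 (1.37 ± 0.11), which activates RhoA at the cleavage furrow. Of 27 DNA repair and replication checkpoint genes 25 rose (26 adjusted over the list alone, median 1.01, camera adjusted p = 7.07e-21), led by Rad51ap1 (2.12 ± 0.15) and the checkpoint kinase Chek1 (1.93 ± 0.12). Genes known to restrain the cycle rose too. Of 10 CDK inhibitors and pocket proteins 7 were higher (7 adjusted over the list alone, median 0.61, camera adjusted p = 0.000444). Members included the pocket protein Rbl1 (1.62 ± 0.10) and the CDK4 and CDK6 inhibitor Cdkn2c (1.30 ± 0.20).

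Of 22 p53 targets 11 rose at 24 h (12 adjusted over the list alone, camera adjusted p = 1.61e-06), with a median of 0.44 that was 0.24 without LacZ 24 h replicate 3. Pmaip1, which encodes the BH3-only protein NOXA, rose by 2.53 ± 0.15 and Trp53inp1 by 1.47 ± 0.11. The heat shock genes Hspa1a and Hspa1b, near-identical copies whose reads may be shared, rose by 3.38 ± 0.10 and 2.76 ± 0.11. Sumo2 rose by 2.93 ± 0.80, but has pseudogene copies, and without 4F 24 h replicate 1 its log2 fold change was 2.61 with an adjusted p of 0.0545.

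Sarcomere genes fell at 24 h in 14 of 24 cases (14 adjusted over the list alone, median -0.44, camera adjusted p = 1.30e-06). Myh7, the beta myosin heavy chain, fell with a log2 fold change of -0.93 ± 0.17. Of 19 calcium handling and ion channel genes 11 fell (12 lower and 1 higher adjusted over the list alone, median -0.33, camera adjusted p = 0.000456). Examples were Kcnj11 (-0.62 ± 0.13), a subunit of the ATP-sensitive potassium channel, and Jph2 (-0.59 ± 0.052), which anchors the junctions of the sarcoplasmic reticulum. Cholesterol and fatty acid synthesis genes fell in 15 of 20 cases (16 adjusted over the list alone, median -0.44, camera adjusted p = 3.07e-08). Among these was fatty acid synthase Fasn (-0.92 ± 0.13). Interferon and antiviral response genes were lower in 8 of 22 cases and higher in 1, Cxcl10 (10 and 1 adjusted over the list alone, median -0.37, camera adjusted p = 0.000209). Of its members, the regulator Irf7 stood at -0.997 ± 0.12 and Ifit3 at -0.86 ± 0.093. Glycolysis genes were lower in 7 of 18 cases (9 adjusted over the list alone, median -0.15, camera adjusted p = 0.00578, adjusted p = 0.233 with an estimated correlation). This list was no longer called after the correction for GC content, while its median was -0.21 without the low-complexity libraries. Of 31 nuclear genes of oxidative phosphorylation 1 was lower, Uqcrc1, a call that ended after the GC correction, and none higher (0 lower adjusted over the list alone, camera adjusted p = 0.599, but 6 lower with an adjusted p of 0.0417 without the low-complexity libraries), while tricarboxylic acid cycle genes went both ways (4 higher and 3 lower of 17, 5 and 3 adjusted over the list alone, camera adjusted p = 0.811), as did fatty acid oxidation genes (3 higher and 6 lower of 27, 3 and 6 adjusted over the list alone, camera adjusted p = 0.209).

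Markers of other heart cell types were mostly level or lower at 24 h. Smooth muscle and pericyte markers were lower in 6 of 8 cases and higher in 1, Rgs5 (6 and 1 adjusted over the list alone, median -0.45, camera adjusted p = 0.00255, adjusted p = 0.145 with an estimated correlation). After the GC correction 3 were lower and 0 higher. Among the members, the pericyte receptor Pdgfrb stood at -0.88 ± 0.10. Endothelial markers were lower in 4 of 13 cases, Pecam1, Vwf, Flt1 and Eng (4 adjusted over the list alone, camera adjusted p = 0.304) and macrophage markers in 1 of 12, Cd68 (1 adjusted over the list alone, camera adjusted p = 0.357). Fibroblast markers had 1 higher, Postn, and 3 lower, Col1a1, Col3a1 and Pdgfra, of 14 (1 and 3 adjusted over the list alone) with a median of -0.21 (camera adjusted p = 0.132). Of the endothelial, macrophage and fibroblast genes just named, only Cd68 and Col1a1 were called under every alternative tried short of a minimum fold change. Vwf (-0.30), Flt1 (-0.27), Postn (0.34) and Pdgfra (-0.19) were among those not called without LacZ 24 h replicate 3. Without the low-complexity libraries macrophage markers were lower in 7 of 12, with a median of -0.39 and an adjusted p of 0.00347. Without LacZ 24 h replicate 3 the fibroblast median was -0.48 with an adjusted p of 0.00196, and after the GC correction -0.31 with an adjusted p of 0.0332. Log2 fold changes at 24 h fell with the GC content of genes (rank correlation across genes, which are not independent replicates, -0.32). The number of genes called at 24 h was 2334 when only the 6 libraries of that time were fitted, and 5825 without the low-complexity libraries, a setting chosen after the data were seen.

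The same comparison at 48 h asked what had changed a day later. The replication and mitosis genes were again higher with 4F, and several genes of the thin filament and Z-disc were much lower. Lmod2, which sets the length of thin filaments, fell from 37.1 ± 0.884 to 6.998 ± 0.453 FPKM, a log2 fold change of -2.25 ± 0.064. The Z-disc protein gene Csrp3 had a log2 fold change of -1.73 ± 0.074, the cardiac actin gene Actc1 one of -1.68 ± 0.13 and the natriuretic peptide gene Nppb one of -2.13 ± 0.31. Cdt1 rose by 2.20 ± 0.19 and Aurka by 2.01 ± 0.084. By limma 4619 genes were called, 1949 higher and 2670 lower, of which 324 and 179 moved by at least 1 on the log2 scale.

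Of 45 G1/S and DNA replication genes 42 rose at 48 h (44 adjusted over the list alone, median 1.23, camera adjusted p = 2.30e-34). In that list, the E2F activator E2f2 stood at 2.09 ± 0.13 and the origin licensing gene Cdc6 at 2.03 ± 0.088. G2/M and mitosis genes rose in 32 of 35 cases (33 adjusted over the list alone, median 1.05, camera adjusted p = 1.62e-22). Members included the CDK1-activating phosphatase Cdc25c (1.57 ± 0.15) and the transcription factor Foxm1 (1.53 ± 0.079). Of 13 cytokinesis genes 10 rose (12 adjusted over the list alone, median 0.53, camera adjusted p = 4.31e-09). Examples were Racgap1 (1.73 ± 0.10) and Kif20a (1.57 ± 0.074). DNA repair and replication checkpoint genes rose in 19 of 27 cases (20 adjusted over the list alone, median 0.57, camera adjusted p = 2.88e-11). Of 22 p53 targets 12 rose (13 adjusted over the list alone, median 0.37, camera adjusted p = 5.74e-07). Among these was Bbc3, which encodes PUMA, at 1.44 ± 0.27. CDK inhibitors and pocket proteins rose in 5 of 10 cases (5 adjusted over the list alone, median 0.55, camera adjusted p = 0.00394, adjusted p = 0.0794 with an estimated correlation). Of its members, Cdkn1a, which encodes p21, stood at 1.20 ± 0.074. Of the named genes, those that rose most at 48 h were Gapdh (4.32 ± 0.46), the non-coding Rn7sk (4.07 ± 0.48) and clustered histone genes such as Hist1h2bj (3.33 ± 0.31). These have near-identical copies elsewhere in the genome, so their values are uncertain. A non-coding gene model, Gm23935, moved with them, from 3587 ± 453 FPKM with LacZ to 11846 ± 1145 with 4F at 48 h.

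Sarcomere genes fell at 48 h in 17 of 24 cases (17 adjusted over the list alone, median -0.65, camera adjusted p = 5.80e-09). Calcium handling and ion channel genes were lower in 13 of 19 and higher in 1, Kcnh2 (13 and 1 adjusted over the list alone, median -0.45, camera adjusted p = 0.000128). Among the members, the SERCA regulator gene Pln stood at -1.61 ± 0.16 and Gja1, which encodes connexin 43, at -1.36 ± 0.18. Cholesterol and fatty acid synthesis genes fell in 12 of 20 cases (14 lower and 1 higher adjusted over the list alone, median -0.42, camera adjusted p = 2.04e-05), led by Hmgcs1 (-1.41 ± 0.10). Interferon and antiviral response genes fell in 8 of 22 (8 adjusted over the list alone, median -0.28, camera adjusted p = 0.00846), a call that ended with library complexity as a covariate (adjusted p = 0.0538). Nuclear genes of oxidative phosphorylation (2 higher and 3 lower of 31, 1 and 3 adjusted over the list alone, camera adjusted p = 0.989), the tricarboxylic acid cycle (2 and 3 of 17, 2 and 4 adjusted over the list alone, camera adjusted p = 0.375), fatty acid oxidation (2 and 9 of 27, 2 and 10 adjusted over the list alone, camera adjusted p = 0.117) and glycolysis (5 and 2 of 18, 6 and 2 adjusted over the list alone, camera adjusted p = 0.117) were not called as lists.

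Markers of other heart cell types moved apart at 48 h. Fibroblast markers fell in 13 of 14 cases (13 adjusted over the list alone, median -0.83, camera adjusted p = 4.39e-06, adjusted p = 0.0736 with an estimated correlation). Members included the collagen cross-linking enzyme Lox (-1.59 ± 0.063) and decorin, Dcn (-1.07 ± 0.17). Endothelial markers rose in 8 of 13 (9 adjusted over the list alone, median 0.62, camera adjusted p = 2.45e-06). Examples were Robo4 (1.26 ± 0.059) and VE-cadherin, Cdh5 (0.80 ± 0.10). Macrophage markers rose in 7 of 12 (9 adjusted over the list alone, median 0.96, camera adjusted p = 5.59e-05, adjusted p = 0.0804 with an estimated correlation). Among these were the complement gene C1qb (1.24 ± 0.30) and Adgre1 (1.01 ± 0.093), which encodes F4/80. Smooth muscle and pericyte markers were lower in 4 of 8, Cnn1, Pdgfrb, Abcc9 and Myh11, the last no longer called at -0.46 without 4F 48 h replicate 2 (4 adjusted over the list alone, median -0.34, camera adjusted p = 0.0112, adjusted p = 0.156 with an estimated correlation). At 48 h log2 fold changes rose with GC content (rank correlation across genes 0.30), the opposite of 24 h. Without the low-complexity libraries, which leaves 1 library of 4F at 48 h that is assumed to vary like the other groups, 5993 genes were called.

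At 72 h, the last time point, contractile genes were again lower with 4F, now with a median log2 fold change of -1.60. Myl2, the ventricular regulatory myosin light chain, fell from 464 ± 11.6 to 67.7 ± 5.09 FPKM, a log2 fold change of -2.76 ± 0.14. Skeletal actin Acta1 (-2.75 ± 0.14) and the Z-disc genes Actn2 (-2.40 ± 0.12) and Myoz2 (-2.39 ± 0.20) fell as well. Among the largest increases were Apoe (2.78 ± 0.45) and lysozyme Lyz2 (2.60 ± 0.51), genes abundant in macrophages, endothelin Edn1 (2.31 ± 0.14) and apelin, Apln, which rose from 43.3 ± 1.92 to 216 ± 2.10 FPKM. The proliferation marker Mki67 rose by 2.17 ± 0.35. By limma 6244 genes were called, 3464 higher and 2780 lower, of which 592 and 305 moved by at least 1 on the log2 scale. The split was 3959 higher and 2333 lower when scaled to recovered reads, but 3054 and 3311 with quantile normalization and 2531 and 2784 after the GC correction. Hist1h2bn was listed at 0 in the LacZ libraries and stood at 7.81 ± 1.07 FPKM with 4F.

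Of 45 G1/S and DNA replication genes 42 rose at 72 h (43 adjusted over the list alone, median 1.03, camera adjusted p = 5.48e-20). Members included the sliding clamp Pcna (1.63 ± 0.10). G2/M and mitosis genes rose in 34 of 35 cases and fell in 1, the securin gene Pttg1 (34 and 1 adjusted over the list alone, median 1.25, camera adjusted p = 6.14e-20). In that list, Kif11 stood at 2.05 ± 0.12. All 13 cytokinesis genes rose (13 adjusted over the list alone, median 1.31, camera adjusted p = 4.72e-10), led by Cep55 (2.02 ± 0.093) and Ect2 (1.98 ± 0.11). Of 27 DNA repair and replication checkpoint genes 26 rose (26 adjusted over the list alone, median 0.97, camera adjusted p = 6.80e-13). CDK inhibitors and pocket proteins were higher in 7 of 10 and lower in 1, Cdkn2b (7 and 1 adjusted over the list alone, median 0.60, camera adjusted p = 0.0124, adjusted p = 0.105 with an estimated correlation). Of 22 p53 targets 15 rose (15 adjusted over the list alone, median 0.45, camera adjusted p = 1.78e-05). Of its members, Pmaip1 stood at 2.21 ± 0.15 and Mdm2, the ubiquitin ligase that degrades p53, at 1.26 ± 0.057.

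Sarcomere genes fell at 72 h in 20 of 24 cases and rose in 1, Nexn (21 and 1 adjusted over the list alone, median -1.60, camera adjusted p = 1.66e-15). After the GC correction 22 were lower and 0 higher. Calcium handling and ion channel genes were lower in 13 of 19 and higher in 2, the potassium channel genes Kcnj2 and Kcnj3 (15 and 2 adjusted over the list alone, median -0.57, camera adjusted p = 4.40e-06). With the GC correction 15 were lower and 0 higher. Among the members, calsequestrin Casq2 stood at -1.55 ± 0.092 and the ryanodine receptor Ryr2 at -1.33 ± 0.16. Transcripts of energy metabolism were lower in several lists. Nuclear genes of oxidative phosphorylation were lower in 22 of 31 (23 adjusted over the list alone, median -0.59, camera adjusted p = 5.15e-09, adjusted p = 0.0718 with an estimated correlation). Examples were Uqcrc1 (-0.91 ± 0.060) of complex III and Sdhb (-0.85 ± 0.093) of complex II. Tricarboxylic acid cycle genes fell in 11 of 17 (11 adjusted over the list alone, median -0.37, camera adjusted p = 2.44e-05). Fatty acid oxidation genes were lower in 14 of 27 and higher in 3, Cd36, Ppargc1a and Pdk4 (14 and 4 adjusted over the list alone, median -0.34, camera adjusted p = 0.00192). The GC correction gave 17 lower and 2 higher. In that list, the fatty acid binding protein Fabp3 stood at -1.55 ± 0.16. Glycolysis genes were lower in 13 of 18 and higher in 1, Slc2a1 (13 and 1 adjusted over the list alone, median -0.40, camera adjusted p = 0.000124, adjusted p = 0.101 with an estimated correlation). Of its members, the muscle phosphofructokinase Pfkm stood at -0.80 ± 0.060.

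Cholesterol and fatty acid synthesis genes fell at 72 h in 17 of 20 cases (17 lower and 1 higher adjusted over the list alone, median -0.74, camera adjusted p = 1.14e-09), led by the desaturases Scd2 (-1.79 ± 0.049) and Scd1 (-1.67 ± 0.084). Interferon and antiviral response genes fell in 14 of 22 and rose in 1, Cxcl10 (15 and 1 adjusted over the list alone, median -0.58, camera adjusted p = 8.71e-06), with Isg15 falling from 48.5 ± 14.7 to 12.1 ± 1.78 FPKM. The members of the lists named as exceptions at 24, 48 and 72 h and for the average were singled out after their values were seen.

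Endothelial markers rose at 72 h in 11 of 13 cases (11 adjusted over the list alone, median 1.43, camera adjusted p = 3.09e-07). Members included the transcription factor Erg (2.08 ± 0.13), Emcn (2.01 ± 0.10) and Cdh5 (1.65 ± 0.10). The other 2, Tek and Flt1, singled out after their values were seen, had log2 fold changes of 0.21 ± 0.15 (limma adjusted p = 0.252) and 0.012 ± 0.12 (limma adjusted p = 0.947). Macrophage markers rose in 10 of 12 (11 adjusted over the list alone, median 1.43, camera adjusted p = 1.95e-05, adjusted p = 0.0718 with an estimated correlation). Examples were Tyrobp (2.17 ± 0.52) and the mannose receptor Mrc1 (1.996 ± 0.087). Fibroblast markers fell in 11 of 14 (11 adjusted over the list alone, median -0.79, camera adjusted p = 4.32e-05, adjusted p = 0.0981 with an estimated correlation). Among the members, the collagen genes Col1a1 stood at -1.71 ± 0.087 and Col1a2 at -1.20 ± 0.19. Smooth muscle and pericyte markers were lower in 6 of 8 and higher in 1, Rgs5 (6 and 1 adjusted over the list alone, median -0.69, camera adjusted p = 0.000404, adjusted p = 0.0754 with an estimated correlation). After the GC correction 5 were lower and 0 higher. These marker changes stand beside the falls in sarcomere and metabolic genes. Without the low-complexity libraries 8205 genes were called at 72 h, and log2 fold changes fell with GC content (rank correlation across genes -0.38).

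**Figure D2:**
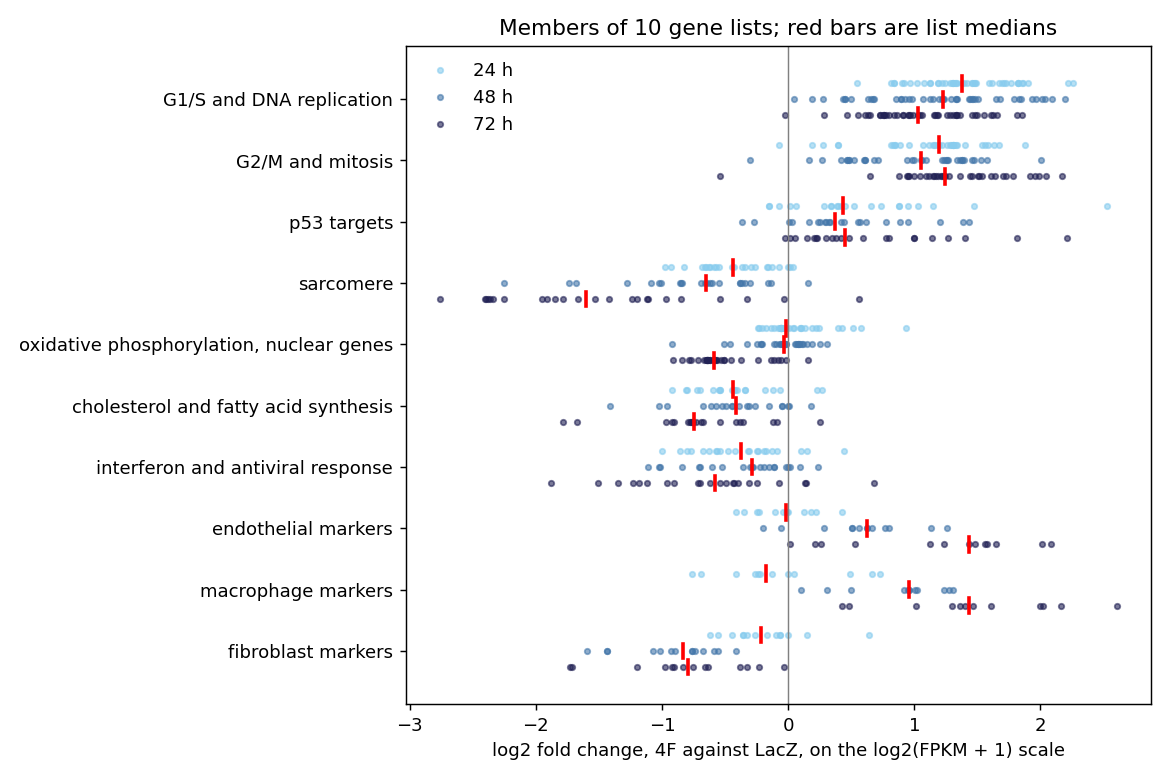
Log2 fold change of 4F against LacZ on the log2(FPKM + 1) scale (x axis) for the members of 10 gene lists (y axis), 1 point per gene, at 24, 48 and 72 h from light to dark blue, with red bars at list medians. The sarcomere median moved from -0.44 at 24 h to -1.60 at 72 h, and the endothelial median from -0.017 to 1.43.

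Calls were compared between the times. Of the genes called higher, 1526 were shared between 24 and 72 h, where independent lists of these sizes would share 507, and 27 genes were higher at 24 h but lower at 72 h. For 24 and 48 h 682 were shared against 285 for independent lists, but 484 were higher at 24 h and lower at 48 h, against 391. Another 864 were lower at 48 h and higher at 72 h, against 678. In the other direction 209 were lower at 24 h and higher at 48 h, against 262, and 240 higher at 48 h and lower at 72 h, against 397. Between 48 and 72 h 933 higher and 877 lower genes were shared, against 495 and 544. Log2 fold changes were correlated with GC content alike at 24 and 72 h and opposite at 48 h. Sharing between 24 and 72 h and the opposite calls of 484 and 864 follow that direction. The opposite calls of 209 and 240 and the sharing between 48 and 72 h do not. After the GC correction 984 higher genes were shared between 24 and 72 h against 281, and 802 between 24 and 48 h against 220. Then 109 were higher at 24 h and lower at 48 h against 236, and 230 lower at 48 h and higher at 72 h against 393. Before the correction, of the genes called lower, 1117 were shared between 24 and 72 h against 373. The comparisons at different times use different LacZ libraries. The low-complexity libraries lie in LacZ at 24 and 72 h but in 4F at 48 h. That follows the same direction as the GC trend, and the overlaps were not counted without those libraries. Called in the same direction at all 3 times were 538 higher and 423 lower genes.

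Averaged over the 3 times, the cell cycle lists were higher with 4F, and the contractile and lipid synthesis lists were lower. All 45 G1/S and DNA replication genes were higher (45 adjusted over the list alone, median 1.22, camera adjusted p = 1.54e-35), and Cdt1 had an average log2 fold change of 2.02 ± 0.11. Of 35 G2/M and mitosis genes 34 were higher and 1 lower, Pttg1 (34 and 1 adjusted over the list alone, median 1.17, camera adjusted p = 1.07e-26). Sarcomere genes were lower in 23 of 24 (23 adjusted over the list alone, median -0.81, camera adjusted p = 1.82e-16). In that list, Actc1 stood at -1.54 ± 0.074. Cholesterol and fatty acid synthesis genes were lower in 18 of 20 (18 adjusted over the list alone, median -0.54, camera adjusted p = 4.45e-11). Of its members, Scd2 stood at -1.12 ± 0.028. Interferon genes were lower in 17 of 22, with 1 higher, Cxcl10 (17 and 1 adjusted over the list alone, median -0.47, camera adjusted p = 4.29e-06). By limma 6255 genes were called on average, 3102 higher and 3153 lower. The split was 3690 and 2542 when scaled to recovered reads and 2819 and 3346 after the GC correction. There were 7640 without the low-complexity libraries. Of the 33 lists tested, 26 were called, 17 of them also with an estimated correlation.

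**Figure D3:**
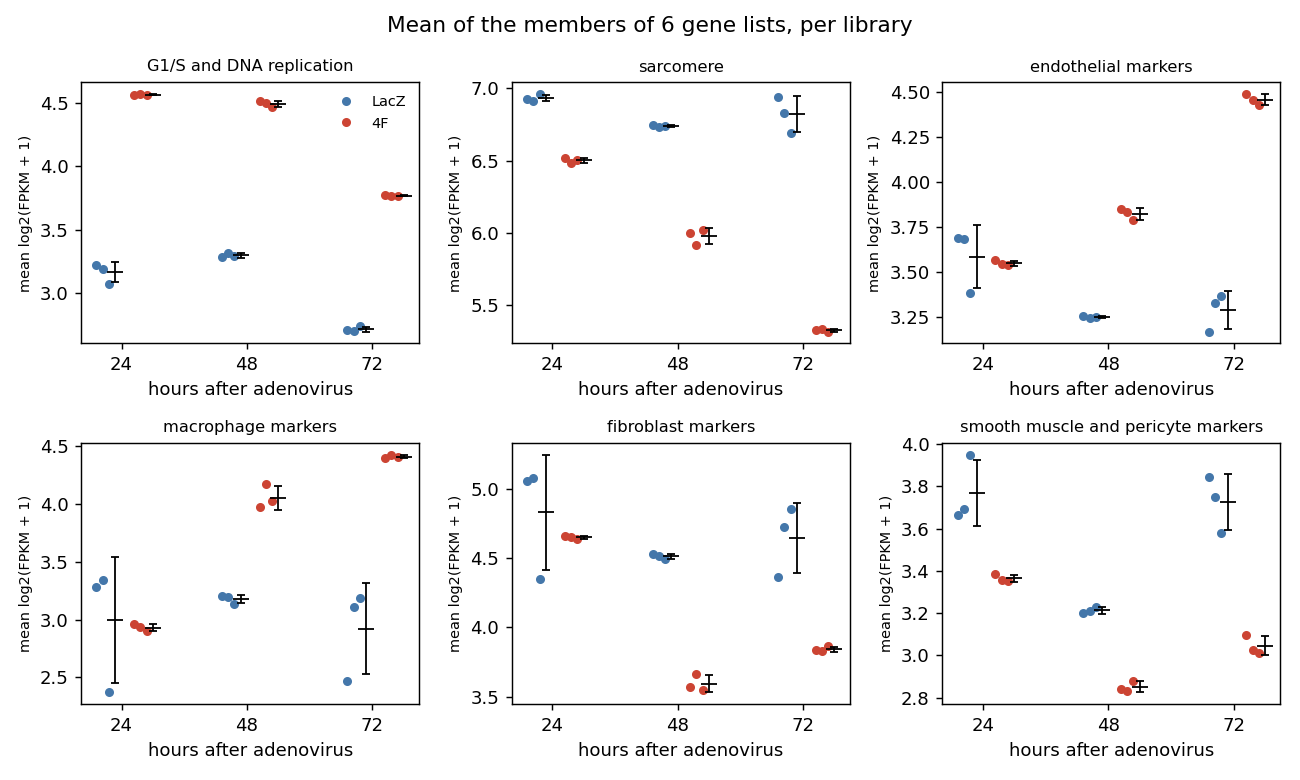
Mean log2(FPKM + 1) over the members of 6 gene lists (y axis) in each library against hours after adenovirus (x axis), LacZ in blue and 4F in red, where each point is 1 library and black marks are the mean ± SD of 3 libraries. Sarcomere means at 72 h were 5.32 to 5.34 with 4F and 6.69 to 6.94 with LacZ, and macrophage means were 4.40 to 4.43 with 4F and 2.47 to 3.19 with LacZ.

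Differences between the effects at 72 h and 24 h tested whether the response changed with time. The effect of 4F on contractile and oxidative genes was lower at 72 h than at 24 h, and that on macrophage and endothelial genes was higher. Apoe differed by 3.001 ± 0.64 on the log2 scale, the protease gene Ctss by 2.85 ± 0.36 and Myl2 by -2.69 ± 0.20. Sarcomere genes were lower in 17 of 24 and higher in 1, Nexn, singled out after its value was seen (17 and 1 adjusted over the list alone, median -1.06, camera adjusted p = 2.16e-16). Nuclear genes of oxidative phosphorylation were lower in 17 of 31 (20 adjusted over the list alone, median -0.58, camera adjusted p = 5.55e-13) and tricarboxylic acid cycle genes in 10 of 17 (14 adjusted over the list alone, median -0.42, camera adjusted p = 6.06e-09). Among these was Cs, citrate synthase, at -0.55 ± 0.082. Endothelial markers were higher in 10 of 13 (11 adjusted over the list alone, median 1.44, camera adjusted p = 4.37e-14). Among the members, Emcn stood at 1.83 ± 0.14. Macrophage markers were higher in 7 of 12 (8 adjusted over the list alone, median 1.59, camera adjusted p = 4.82e-09). In that list, C1qb stood at 2.79 ± 0.42. The rise of G1/S and DNA replication genes was smaller at 72 h, with 14 of 45 lower (20 adjusted over the list alone, median -0.37, camera adjusted p = 1.72e-07). Members included E2f1 at -0.93 ± 0.16. By limma 1914 genes differed, 1052 higher and 862 lower, but 879 and 963 after the GC correction and 697 and 781 with a filter at FPKM 5. The count was 3891 without the low-complexity libraries.

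Between the effects at 48 h and 24 h, Rn7sk (3.80 ± 0.68), Gapdh (3.79 ± 0.66), the mitochondrial ribosomal RNA gene mt-Rnr2 (2.85 ± 0.77) and the histone genes Hist1h2bn (2.50 ± 0.34) and Hist1h3c (2.38 ± 0.52) moved highest, all transcripts with copies or of high abundance whose values are uncertain. Hspa1a (-2.18 ± 0.14) and the epidermal envelope genes Lce1h (-2.10 ± 0.43) and Scel (-2.09 ± 0.29) were among the lowest. So were Sumo2 (-4.22 ± 1.13), whose call ended without the low-complexity libraries, and Lce1g (-2.16 ± 0.58), whose call ended with a pseudocount of 0.1. By limma 3834 genes differed, 1613 higher and 2221 lower. The split was 1790 and 1706 with quantile normalization and 1299 and 2578 when scaled to recovered reads. Of the 3834 genes 1482 were still called in the same direction after the correction for GC content. The count was 1895 after that correction, with which log2 fold changes were correlated in opposite directions at the 2 times, and 5641 without the low-complexity libraries.

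LacZ at 72 h was compared with LacZ at 24 h to show what changed with time under the control virus. Cell cycle genes fell and antiviral genes rose. The thymidine kinase gene Tk1 fell from 7.42 ± 1.46 to 2.72 ± 1.27 FPKM (-1.22 ± 0.20) and Foxm1 with a log2 fold change of -1.06 ± 0.079, while Usp18, which restrains interferon signalling, rose by 1.71 ± 0.22 and Oasl2 by 1.39 ± 0.11. The imprinted transcript H19, abundant in fetal tissue, fell from 112 ± 1.19 to 21.6 ± 2.20 FPKM. Acta1 rose by 2.02 ± 0.14. By limma 3946 genes were called, 2027 higher and 1919 lower, but 1870 and 1960 after the GC correction, 1267 and 1548 with a filter at FPKM 5 and 2473 and 2725 without LacZ 24 h replicate 3.

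Of 45 G1/S and DNA replication genes 31 fell with time under LacZ and 1 rose, Ccne2, singled out after its value was seen (31 and 1 adjusted over the list alone, median -0.52, camera adjusted p = 2.53e-11). G2/M and mitosis genes fell in 22 of 35 (23 adjusted over the list alone, median -0.41, camera adjusted p = 1.32e-09) and cytokinesis genes in 9 of 13 (9 adjusted over the list alone, median -0.58, camera adjusted p = 1.75e-06). Of its members, Cdca8 stood at -0.85 ± 0.12. Interferon and antiviral response genes rose in 18 of 22 (19 higher and 2 lower adjusted over the list alone, median 1.01, camera adjusted p = 3.00e-11). Fatty acid oxidation genes fell in 13 of 27 and rose in 1, Cpt1a, also singled out (13 and 1 adjusted over the list alone, median -0.27, camera adjusted p = 0.000740). Among the members, Acsl1 stood at -0.69 ± 0.10. In all, 12 of the 33 lists were called lower and 2 higher. Endothelial markers were lower in 6 of 13 after the GC correction (median -0.24, camera adjusted p = 0.0115). The p53 targets had a median of 0.27, or 0.11 without LacZ 24 h replicate 3. Sarcomere genes were not called as a list (3 higher and 6 lower of 24, 3 and 6 adjusted over the list alone, camera adjusted p = 0.335). The number of genes called was 777 when only these 6 libraries were fitted, and Tk1 and Cdca8 were then not called. It was 5618 without the low-complexity libraries, 1 of which lies in each group.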

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

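The tests of a smaller share of cardiomyocytes and of larger shares of endothelial cells and macrophages were chosen after the marker values were seen, as were the 10% limit for low complexity, the GC correction and the requirement that a GC ratio hold without each library. The marker test first covered only the weaker markers of each list. It was widened to every measured marker after that first result was seen, which brought in Tek, Flt1 and Eng and left the endothelial question open.

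The effect of 4F differed between times by a test of the difference itself. It differed in 3834 genes between 48 and 24 h and in 1914 between 72 and 24 h. Between 48 and 24 h the log2 differences were 3.80 for Rn7sk, 3.79 for Gapdh, 2.85 for mt-Rnr2, 2.50 for Hist1h2bn and 2.38 for Hist1h3c. They were -2.18 for Hspa1a, -2.16 for Lce1g (lost with a pseudocount of 0.1), -2.10 for Lce1h and -2.09 for Scel. Sumo2 differed by -4.22, a call lost without the low-complexity libraries (-4.01, adjusted p = 0.0701). Between 72 and 24 h they were 3.001 for Apoe, 2.85 for Ctss, 2.79 for C1qb, 2.44 for Marco and 2.39 for Mpeg1, and -2.69 for Myl2, -2.47 for Cidea, -2.13 for Myoz2, -2.11 for Hspa1a and -2.09 for Myl3.

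Of the gene lists, 15 differed between 72 and 24 h. Medians of the differences were -0.37 for G1/S and DNA replication, -1.06 for sarcomere, -0.25 for fatty acid oxidation (camera adjusted p = 0.0169), -0.58 for oxidative phosphorylation, -0.42 for the tricarboxylic acid cycle, -0.24 for cholesterol and fatty acid synthesis (camera adjusted p = 0.000553), -0.24 for interferon (camera adjusted p = 0.0169, lost with a pseudocount of 0.1, adjusted p = 0.118), 1.44 for endothelial and 1.59 for macrophage markers. The other 6 were lost with an estimated correlation. The cytokinesis median was 0.22 (0.15 without LacZ 72 h replicate 3), with adjusted p = 0.106 with an estimated correlation. The calcium handling median was -0.16 (-0.25 after the GC correction), with adjusted p = 0.0725 with an estimated correlation. Glycolysis stood at -0.28 (-0.18 without LacZ 72 h replicate 1), with adjusted p = 0.279 with an estimated correlation. Fibroblast markers stood at -0.51, with adjusted p = 0.144 with an estimated correlation. The inflammatory median was 0.55, with adjusted p = 0.303 with an estimated correlation, and 0.38, 0.28 and 0.28, no longer called, without LacZ 24 h replicate 1, LacZ 24 h replicate 2 or LacZ 72 h replicate 1. The smooth muscle median was -0.21, with adjusted p = 0.279 with an estimated correlation, and -0.17, -0.18 and -0.20, no longer called, without those same libraries, and -0.22 with an adjusted p of 0.0523 after the GC correction.

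Sarcomere genes had a median log2 fold change of -1.60 at 72 h. Without the low-complexity libraries it was -1.54 and after the GC correction -1.55, which argues against either as the whole cause. If only the share of cardiomyocytes fell and the other cell types kept their proportions, the markers of all other cell types would rise alike. The endothelial median exceeded the fibroblast median by at least 2.17 in every leave-one-out fit, which argues against that case. Shares of several cell types that changed at once could give such values, so a smaller share of cardiomyocytes stays open. Lower transcript levels within cardiomyocytes that received 4F may account for the fall, a hypothesis that was not itself tested. A preparation difference between whole groups was not tested either and stays open.

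Endothelial and macrophage markers were higher with 4F at 72 h. In 10000 random lists matched on mean expression the higher of the 2 medians was -0.015, and after the GC correction the lower of the marker medians was 1.48, which argues against a general rise of such genes and against GC content. If the share of a cell type grew, all its markers would rise by about the same factor. Bounds for this test came from voom on the recovered reads, where the endothelial median was 1.62, against 1.43 on log2(FPKM + 1). Of 13 endothelial markers 3 (Tek, Flt1 and Eng, with 95% upper bounds of 0.55, 0.27 and 0.42) stayed under 0.5 of that median rise of 1.62. A larger share of endothelial cells and a change within them thus cannot be told apart, since these markers may also be regulated or expressed by other cells. Of 12 macrophage markers, 10 on recovered reads and the others on log2(FPKM + 1), 0 stayed under 0.5 of their median rise of 1.55. Cd14, with an upper bound of 0.85 on log2(FPKM + 1), came near. On recovered reads the rises were unequal, from 0.93 for Fcgr1 to 3.21 for Mrc1, both weak with LacZ (0.81 and 0.56 FPKM). Members with wide bounds or with rises above the median pass this test. It thus cannot tell a larger share of macrophages from a change within those cells, and both stay open.

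Log2 fold changes followed GC content with opposite signs, with rank correlations across genes of -0.32, 0.30 and -0.38 at 24, 48 and 72 h. Without the low-complexity libraries the correlations at 24 and 72 h were -0.484 and -0.441. These values argue against those libraries as the whole cause at 24 and 72 h. At 48 h the correlation was then 0.359. It rested on 1 remaining 4F library, 4F 48 h replicate 2, which had the highest GC correlation of that time (0.589). The 48 h value thus cannot decide whether the low-complexity libraries set the trend at 48 h. Without the genes of the fixed lists the correlation nearer to 0 of those at 48 and 72 h was 0.304. These lists held only 541 genes, against 13625 with a known GC content, too few for their removal to decide whether such genes set the trend. The difference between 4F and LacZ in GC correlation was at least 1.05 times the widest range within a group at each time (1.03 at the lowest without any 1 library), which argues narrowly against preparation of single libraries. All 6 libraries of 48 h had correlations of 0.50 to 0.59, against -0.55 to 0.17 in the other 12. A preparation difference between whole times or groups is confounded with them and stays open.

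Other splits of the same libraries were tested. For 24, 48 and 72 h the 10 possible splits are too few for a share under 0.05, and the real split gave 3827, 4619 and 6244 genes against at most 0, 1 and 2 in the others (1 of 10 each). For the average, 1 of 100 splits reached the real 6255, with 4227 as the highest other. For the 2 differences, what an additive fit of treatment and time left over was exchanged between times within each treatment, which tests for equal effects at both times. For 48 h minus 24 h it was 1 of 100 (3834, highest other 1) and for 72 h minus 24 h 1 of 100 (1914, highest other 1736, near the real count). For these 3 counts the real grouping was thus the only 1 of 100 to reach its count, a share under 0.05. Such exchanges cannot address a preparation difference between whole times or groups. For LacZ over time 2 of 10 splits reached the real 3946, again too few for a share under 0.05, and the other gave 4384. It set LacZ 24 h replicates 1 and 2 and LacZ 72 h replicate 3 against the rest, following library complexity, with 15.8% to 19.8% of detected genes at 1 to 3 reads on one side and 2.45% to 13.3% on the other. With that share as a covariate 6258 genes were called. A check chosen after this split was seen found no sign of exchanged labels. Set on a scale from LacZ 24 h (0) to LacZ 72 h (1) by the other libraries, LacZ 24 h replicate 3 lay at 0.118 and LacZ 72 h replicate 3 at 0.852.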

How the results depend on the processing

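Scaling to recovered reads, voom, leaving out the low-complexity libraries, the complexity covariate and the GC correction were chosen after the data were seen. The cause of a change was not tested unless given. Requiring a log2 fold change of at least 1, a stricter limit by construction, left 365, 503 and 897 genes at 24, 48 and 72 h, 361 for the average, 628 for 48 h minus 24 h, 369 for 72 h minus 24 h and 362 for LacZ over time. With array weights per library the counts were 8296 at 24 h, 11146 at 72 h, 6742 and 8129 for the 2 differences and 10677 for LacZ over time, but the weights did not settle (541.5 for LacZ 72 h replicate 2), so these are no guide. With only the groups compared, fewer libraries, 2334 genes were called at 24 h and 777 for LacZ over time. Without the low-complexity libraries the counts were 5825 at 24 h and 3891 for 72 h minus 24 h. With complexity as a covariate they were 4088 for 72 h minus 24 h and 6258 for LacZ over time. The GC correction left 1895 for 48 h minus 24 h. It turned the log2 fold changes of Rpe at 72 h (-0.028), Dnajb9 at 72 h (-0.060) and Rpe on average (-0.023). All other counts stayed within 1.5 times. Leaving out 1 library at a time gave 2855 to 4083, 3670 to 4042 and 5309 to 6281 at 24, 48 and 72 h, 5753 to 6959 for the average, 3094 to 4562 and 1395 to 2461 for the 2 differences and 3162 to 5198 for LacZ over time. Of 1782 list tests so repeated, 22 lost and 15 gained a call. Among further medians that moved by over 1.5 times were those that follow. With a pseudocount of 0.1, which widens changes of weak genes by construction, interferon stood at -0.61 and -0.43 at 24 and 48 h, DNA repair at 0.95 at 48 h, epicardial markers at -1.56 (adjusted p = 0.0510) and -1.38 at 48 and 72 h and pro-apoptotic genes at 0.38 at 72 h. Scaled to recovered reads, the 24 h medians of fetal genes and glycolysis were -0.062 and -0.069. The p53 targets at 24 h stood at 0.28 with the complexity covariate. Fetal genes at 24 h stood at -0.28 without LacZ 24 h replicate 3 and at -0.25 with that covariate, with which they stood at -0.35 at 72 h and smooth muscle markers at -0.28 at 24 h. Pro-apoptotic genes stood at 0.26 at 48 h without the low-complexity libraries, at 0.31 with the covariate and at 0.44 at 72 h without LacZ 72 h replicate 3, which also moved ribosome biogenesis at 72 h to 0.25. After the GC correction purine synthesis stood at 0.14 at 24 h and ribosome biogenesis at 0.25 at 72 h. There were 17, 20 and 23 list calls at 24, 48 and 72 h, 26 for the average, 15 for 72 h minus 24 h and 14 for LacZ over time. Of these an estimated correlation ended 43, and the GC correction ended 7 and added 11. The GC correction kept 62.2%, 75.8% and 68.1% of the genes called at 24, 48 and 72 h in the same direction, and 20 were called in the opposite one at 72 h. It kept 83.9% for the average, 38.7% for 48 h minus 24 h, 81.0% for 72 h minus 24 h and 85.0% for LacZ over time. Leaving out the low-complexity libraries kept 95.1%, 88.2% and 97.0% at the 3 times, 94.0% for the average, 86.3% and 97.4% for the 2 differences and 89.6% for LacZ over time. Scaled to recovered reads, 64.8% of the 3923 calls at 24 h were higher, against 52.2%. The GC correction turned the balance of higher and lower calls at 24 h (1516 and 1517), at 72 h (2531 and 2784), for 72 h minus 24 h (879 and 963) and for LacZ over time (1870 and 1960). Quantile normalization turned it at 24 h (1764 and 2138), at 72 h (3054 and 3311) and for 48 h minus 24 h (1790 and 1706). The filter at FPKM 5 turned it at 24 h (1519 and 1524), at 72 h (2213 and 2290), for 72 h minus 24 h (697 and 781) and for LacZ over time (1267 and 1548). Leaving out the low-complexity libraries turned it at 24 h (2795 and 3030) and for LacZ over time (2675 and 2943). The latter also turned with the complexity covariate (3065 and 3193) and without LacZ 24 h replicate 3 (2473 and 2725). The average turned with no filter (3859 and 2937) and when scaled to recovered reads (3690 and 2542). The minimum fold change turned it at 48 h (324 and 179) and for the average (288 and 73), and the array weights at 24 h (3967 and 4329) and for LacZ over time (5110 and 5567). That scaling, a pseudocount of 0.1 and voom moved the median of all genes for 48 h minus 24 h to -0.126, -0.111 and -0.115. Median-ratio scaling moves nothing in these values and tests nothing.

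The replicate numbers did not pair the libraries (45 same-numbered pairs, correlations -0.58 to 0.25, 5 above 0.1, 4 of 18 libraries closest to their own number). With the replicate block 3611, 4404 and 6057 genes were called at 24, 48 and 72 h, 6041 for the average, 3560 and 1719 for the 2 differences and 3685 for LacZ over time. What depth alone limits was not tested. With the spread of these libraries the simulated fit at 24 h recovered 50.7% of changes of 0.5 on the log2 scale.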

Other observations

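The exceptions named here were singled out after their values were seen, and the scaling, complexity and GC settings were chosen after the data were seen. Several stress and synthesis lists moved with 4F. NRF2 targets, genes of the antioxidant response, were higher in 6 of 14 at 24 h (6 adjusted over the list alone, median 0.19, camera adjusted p = 0.00690, adjusted p = 0.119 with an estimated correlation) and in 9 at 72 h with 2 lower (9 and 2 adjusted over the list alone, median 0.68, 0.40 after the GC correction, camera adjusted p = 0.0124, adjusted p = 0.105 with an estimated correlation). Heme oxygenase Hmox1 rose by 1.19 ± 0.11 at 72 h. At 48 h the list was not called (1 higher, 2 lower, 0 and 2 adjusted over the list alone, camera adjusted p = 0.601). Integrated stress response genes rose at 48 h in 5 of 13 with 1 lower (6 and 1 adjusted over the list alone, median 0.52, camera adjusted p = 0.00686, adjusted p = 0.0823 with an estimated correlation). Of its members, Atf3 stood at 1.93 ± 0.20. The list was not called at 24 h (camera adjusted p = 0.527) or 72 h (camera adjusted p = 0.692). Unfolded protein response genes fell at 48 h in 5 of 13 (6 adjusted over the list alone, median -0.25, camera adjusted p = 0.00394). Among the members, the chaperone Hsp90b1 stood at -1.18 ± 0.053. These genes were not called as a list at 24 h (camera adjusted p = 0.357) or 72 h (camera adjusted p = 0.668). Serine and one-carbon synthesis genes rose at 48 h in 6 of 9 (6 adjusted over the list alone, median 0.35, camera adjusted p = 0.00394). In that list, Shmt2 stood at 0.67 ± 0.071. The list was not called at 24 h (camera adjusted p = 0.177, or 0.0319 after the GC correction) or 72 h (camera adjusted p = 0.668). Purine and pyrimidine synthesis genes rose at 48 h in 7 of 16 (8 adjusted over the list alone, median 0.27, camera adjusted p = 0.00394). Of its members, Umps stood at 0.62 ± 0.075. At 24 h 4 rose and 1 fell (4 and 2 adjusted over the list alone, median 0.22, camera adjusted p = 0.0193, adjusted p = 0.0996 with an estimated correlation), a median of 0.14 without LacZ 24 h replicate 3 and 0.18, no longer called, without LacZ 24 h replicate 1, and at 72 h the list was not called (camera adjusted p = 0.505).

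Ribosome biogenesis genes were higher at 72 h in 10 of 21 with 1 lower (10 and 1 adjusted over the list alone, median 0.17, 0.25 without LacZ 72 h replicate 3, camera adjusted p = 0.0335, adjusted p = 0.0706 with an estimated correlation). Among the members, Nop58 stood at 1.13 ± 0.10. These genes were not called as a list at 24 h (camera adjusted p = 0.242) or 48 h (camera adjusted p = 0.149). Pro-apoptotic genes were higher in 7 of 16 at 24 h with 1 lower (8 and 1 adjusted over the list alone, median 0.41, 0.18 without LacZ 24 h replicate 3, adjusted p = 0.235 with an estimated correlation), in 4 at 48 h (4 adjusted over the list alone, median 0.13, 0.11 and no longer called without 4F 48 h replicate 2, adjusted p = 0.336 with an estimated correlation) and in 7 at 72 h with 1 lower, Bak1 (7 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.432 with an estimated correlation). The 72 h call ended without LacZ 72 h replicate 1 (0.17), LacZ 72 h replicate 2 (0.25), 4F 72 h replicate 2 (0.20) or 4F 72 h replicate 3 (0.23). It also ended when scaled to recovered reads (0.29), without the low-complexity libraries (0.17) and with the complexity covariate (0.13), which ended the 24 h call too (0.28). Fetal and stress genes of cardiomyocytes had 6 of 14 lower at 24 h (7 adjusted over the list alone, median -0.14, camera adjusted p = 0.0412, adjusted p = 0.189 with an estimated correlation), no longer called without LacZ 24 h replicate 1 (-0.17), LacZ 24 h replicate 2 (-0.14) or 4F 24 h replicate 3 (-0.12), and 7 lower and 2 higher at 72 h (7 and 3 adjusted over the list alone, median -0.22, camera adjusted p = 0.0253, adjusted p = 0.124 with an estimated correlation). At 48 h they were not called (camera adjusted p = 0.531). The GC correction ended both calls (adjusted p = 0.0561 and 0.0540). Epicardial and mesothelial markers fell in 4 of 6 at 24 h (4 adjusted over the list alone, median -0.65, camera adjusted p = 0.00191). In that list, mesothelin Msln stood at -0.77 ± 0.15. Epicardial and mesothelial markers were lower in 4 at 48 h (4 adjusted over the list alone, median -0.96, -0.93 and no longer called without 4F 48 h replicate 2, adjusted p = 0.0794 with an estimated correlation) and in 4 at 72 h with 1 higher, Wt1 (4 and 1 adjusted over the list alone, median -0.83, adjusted p = 0.0710 with an estimated correlation). The 48 h call also ended with a pseudocount of 0.1 (adjusted p = 0.0510) and with the complexity covariate (0.117), and the 72 h call with that covariate (0.0543) and after the GC correction (0.0950).

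Not called at 24, 48 or 72 h were the pentose phosphate list (camera adjusted p = 0.499, 0.740 and 0.210), hexosamine synthesis (camera adjusted p = 0.304, 0.0519 and 0.578), the inflammatory and NF-kB list (camera adjusted p = 0.452, 0.869 and 0.152), YAP targets (camera adjusted p = 0.102, 0.0918 and 0.730) and mitochondrially encoded genes (camera adjusted p = 0.304, 0.829 and 0.210). Hexosamine synthesis was called lower at 48 h without 4F 48 h replicate 1 (-0.35) or 4F 48 h replicate 3 (-0.36), and YAP targets at 24 h without LacZ 24 h replicate 3 (-0.27). The hexosamine list was also called with the replicate block (-0.35), when scaled to recovered reads (-0.35) and without the low-complexity libraries (-0.39). After the GC correction mitochondrially encoded genes were called lower at 24 h (5 of 13, median -0.47, adjusted p = 0.00963) and at 72 h (9 of 13, median -0.66, adjusted p = 0.000406), and YAP targets at 48 h (4 of 9, median -0.27, adjusted p = 0.0209). Within the inflammatory list Icam1 rose by 0.97 ± 0.26 at 72 h.

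With time under LacZ, Lce1h, a gene of the cornified envelope of skin, rose by 2.88 ± 0.31 and Crct1 by 2.75 ± 0.36 on the log2 scale. The pantetheinase gene Vnn1 (2.57 ± 0.21) and the metalloproteinase Mmp10 (2.63 ± 0.21) rose too. The potassium channel subunit Kcne1 fell with -2.54 ± 0.12. Biosynthetic lists fell, among them serine and one-carbon synthesis (6 of 9 lower, 6 adjusted over the list alone, median -0.70, camera adjusted p = 0.000126), purine and pyrimidine synthesis (9 of 16, 10 adjusted over the list alone, median -0.29, camera adjusted p = 0.000230) and ribosome biogenesis (10 of 21, 12 adjusted over the list alone, median -0.34, camera adjusted p = 0.000320). The serine synthesis enzyme Phgdh fell with -0.85 ± 0.088 and the pyrimidine enzyme Cad with -0.74 ± 0.10, a call that ended with only the 6 LacZ libraries of these times.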
